A study of Homo sapiens with 6 samples.

How the data were processed

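The data are gene expression values of 6 RNA-seq libraries from SACC-83 cells, 3 with an empty vector and 3 with circMYBL1 overexpression, grouped by the sample titles. The genotype labels of the overexpression libraries carry a number that runs on with the replicate, as circMYBL1, circMYBL2 and circMYBL3. The sample titles mark all 3 as overexpression and name no circular RNA. Because the design text names circMYBL1 only, the 3 were kept as replicates, which the genotype labels leave uncertain. Nothing states that same-group libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

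Per the labels' protocols, RNA was extracted with TRIzol, mRNA was purified and fragmented, and libraries were made with an Illumina kit of the NEBNext Ultra series. HISAT2 and the build GRCh38 are named in the submitters' processing notes; the counting tool, the annotation and the versions are not given in the sources used here. The deposited table holds FPKM, that is fragments scaled by gene length and library size, as computed by the authors, for 27328 loci. Of these, 19974 carry Ensembl identifiers and 7354 are named as new genes without positions. No whole-read steps could be recovered from the FPKM values, so depth per library is unknown and no counting error can be given. FPKM divides by the library total, so a few abundant genes can shift the others. The 10 most abundant loci held 9.36% to 13.1% of the summed FPKM. Whether strand was used in counting is not stated, so overlapping and antisense genes cannot be told apart. A total of 4173 loci were at 0 in every library. All 19974 Ensembl identifiers matched GENCODE release 29, which gave positions, length and GC content, and 19883 had a current symbol. The symbols in the table include 17 repeats and 27 date-like forms, so genes were handled by identifier. Pearson's r of log2 values between libraries ranged from 0.915 to 0.990, and no pair of libraries was identical.

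Genes with FPKM of at least 1 in at least 3 of the 6 libraries were kept, 12064 in all, of which 11166 had an Ensembl identifier. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend, 2-sided, Benjamini-Hochberg adjustment), with group as the only term. The threshold was an adjusted p of 0.05, also counted with a fold of at least 2. The groups share replicate numbers, and the labels do not say what a number stands for. After removal of group means, same-numbered libraries correlated at 0.725, 0.881 and 0.529 across genes for numbers 1, 2 and 3, all above the limit of 0.1 set beforehand. Of the differently numbered libraries, vector replicate 3 with overexpression replicate 1 (0.412) and vector replicate 1 with overexpression replicate 3 (0.424) also lay above it, close to the value for number 3, so numbers 1 and 3 are set apart less clearly than number 2. The other 4 lay between -0.818 and -0.552, and each library correlated best with that of its own number. Deviations from a group mean cancel within the group. With number 2 apart in both groups, numbers 1 and 3 thus tend to correlate positively however matched. Passing 0.1 therefore does not test their pairing, which rests on the higher values of the matched libraries. The numbers were therefore taken to pair the libraries, on the evidence of these correlations and not of the labels, and a fit with replicate number as a block was run beside the group-only fit. The replicate number itself was called for 5605 genes, 46.5% of those tested. An exact permutation test of 3 against 3 cannot give a p under 0.1.

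Before the data were examined, 32 gene lists were fixed, and the 29 with at least 3 kept members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move on balance and does not compare them with other genes. Members were also counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. The rule for named genes, set at the same time, took CD44 and MYBL1 always, up to 12 genes per direction past the threshold with non-overlapping ranges and a mean FPKM of at least 2, filled up to 6 by the smallest unadjusted p, and up to 4 members of each list. No gene passed without the block, so the fill supplied the names. Genes named outside the rule are said to be so. List members named by the rule show the range within a list and are no calls unless said: of the 110 that the rule picks, 96 had a log2 fold change that moved by over 1.5 times or turned sign when 1 library was left out, and 30 turned sign.

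The alternatives fixed at that time were pseudocounts of 0.1 and 0.5, no filter, a filter on a mean FPKM of at least 5, TPM, trimmed mean (TMM) factors computed directly, quantile scaling, eBayes without a trend, library weights, the block, and leaving out each library. Count-based tests that had been planned for raw counts were not run, since the file holds none. A lowess correction of each library for GC content and length (span 0.3), each alternative within the block fit, the estimated correlation under each alternative, and the block fit on genes with a known GC content only, were added after seeing the data. The procedure was tested on simulated data over 12064 genes for the overexpression comparison. Without the block, 0% of genes changed by 0.5 on the log2 scale, 5.97% of those changed by 1 and 83.3% of those changed by 2 were recovered, with 0 false calls among 59. With the block the shares were 65.7%, 100% and 100%, with 18 false calls among 195. The simulated values kept the replicate differences of the block fit and added independent normal noise of its fitted size, with 200 genes changed. The block model was thus true in them by construction, and these shares need not hold for the real data. Figures were drawn with matplotlib 3.10.9.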

Results

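Libraries of purified mRNA were compared between SACC-83 cells carrying an empty vector and SACC-83 cells overexpressing circMYBL1, with 3 libraries per group. SACC-83 is an established human cell line from a salivary adenoid cystic carcinoma, and circMYBL1 is a circular RNA named after the transcription factor gene MYBL1. The stated purpose of the sequencing was to find target genes of the circular RNA, and the series title names CD44, a cell-surface receptor for hyaluronan. Levels are given as deposited FPKM, as mean ± SD over the 3 libraries of a group, and log2 fold changes are differences of log2(FPKM + 1), which understate changes of low genes. Summed FPKM per library lay between 371776 (vector replicate 2) and 408826 (overexpression replicate 1). Read depth is unknown from these values. Genome positions are those of GENCODE release 29 on GRCh38.

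The libraries separated by replicate number, and neither of the first 2 principal components set the groups apart. The first principal component held 74.5% of the variance and set the libraries numbered 2 of both groups, at 47.0 and 36.0, apart from the other 4, at -28.6 to -11.8. On component 2, overexpression replicate 3 (-7.62) lay within the range of the vector libraries (-13.2 to -0.154). Same-numbered libraries of the 2 groups were therefore treated as pairs in a further fit with replicate number as a block, and both fits are reported where they differ.

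**Figure D1:**
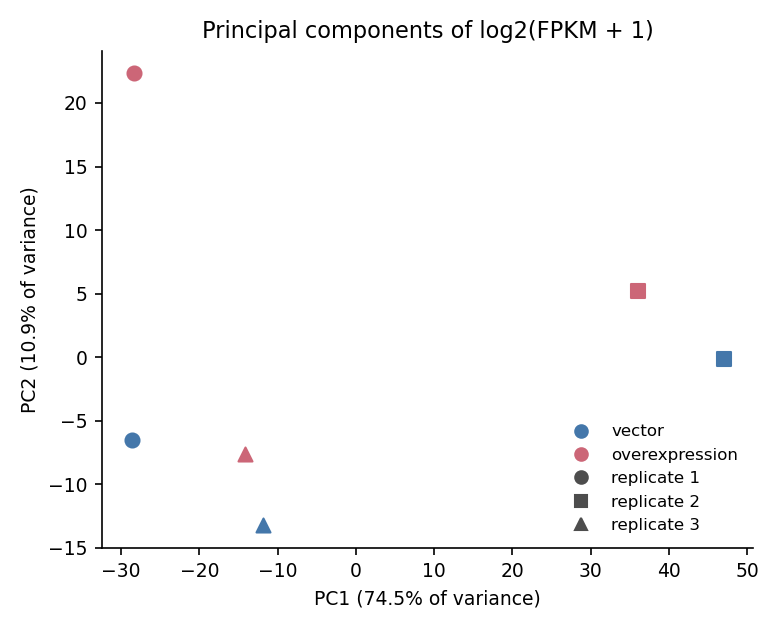
Principal components 1 and 2 of log2(FPKM + 1) for the 6 libraries, with color for the group and marker shape for the replicate number. The square markers, replicate 2 of the vector and overexpression groups, lie at 47.0 and 36.0 on component 1, which holds 74.5% of the variance.

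MYBL1, the host gene of the circular RNA, was higher in each overexpression library than in any vector library. MYBL1 (ENSG00000185697, chromosome 8, 66562175 to 66614247, minus strand) read 9.04, 7.15 and 10.3 FPKM in vector replicates 1, 2 and 3, and 359, 44.0 and 2025 FPKM in overexpression replicates 1, 2 and 3. The ratio within a pair was thus 39.7, 6.16 and 197, so the 3 overexpression libraries differed from each other by more than the vector libraries did. The log2 fold change was 5.04 (SE 1.21, limma, adjusted p = 1.0), and with the replicate block MYBL1 rose (SE 0.66, adjusted p = 0.0225). That call ended without replicate 1 of both groups (adjusted p = 0.0587), without a filter on low values (0.814), without a trend (0.0883) and after GC and length correction (0.117). This gene-level value sums all reads assigned to MYBL1 and does not measure the circle. Whether the added reads come from the circle, its construct or linear MYBL1 cannot be told from these values. The rise is therefore no evidence that the cells' own MYBL1 gene was induced. The related genes MYBL2 (90.2 ± 15.6 against 93.1 ± 13.2 FPKM) and MYB (0.886 ± 0.277 against 0.984 ± 0.267 FPKM) gave log2 fold changes of 0.05 and 0.07, where MYBL2 was named after its values were seen, and NFIB, a frequent fusion partner of MYB genes in this tumor type, gave -0.09. The list of these 4 genes did not pass (camera, mean log2 fold change 1.27, adjusted p = 0.122), and its mean came from MYBL1, with a median of 0.06. It passed without overexpression replicate 2 (1.60, adjusted p = 0.0395) and, in the block fit, without replicate 2 of both groups (1.61, adjusted p = 1.22e-65). The second fit keeps 2 libraries per group and few residual degrees of freedom, so that p is unreliable. With an estimated correlation the list did not pass in either setting (adjusted p = 0.552 and 0.921).

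CD44 was higher in the overexpression libraries in 3 of 3 pairs, and its test did not pass the adjustment over all genes. CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402, plus strand) measured 119.6 ± 5.87 FPKM in vector libraries and 154 ± 14.1 FPKM in overexpression libraries, and the ranges of the groups did not overlap. The log2 fold change was 0.36 (SE 0.13, limma, adjusted p = 1.0; with the replicate block SE 0.10, adjusted p = 0.445). For this gene, named in advance from the series title, the unadjusted p by limma was 0.0328 without and 0.00472 with the block. The title may itself rest on these libraries, so these p-values need not be an independent test. Ratios within the pairs were 1.26, 1.47 and 1.14. Of the 12 tested genes of the list around CD44 and hyaluronan, 6 were higher and 6 lower, with a mean log2 fold change of 0.05 (camera, adjusted p = 0.689). HYAL2, a hyaluronidase, read 12.9 ± 1.37 against 16.0 ± 1.41 FPKM, while RDX and MSN, which link CD44 to the actin cortex, gave log2 fold changes of -0.16 and -0.09.

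**Figure D2:**
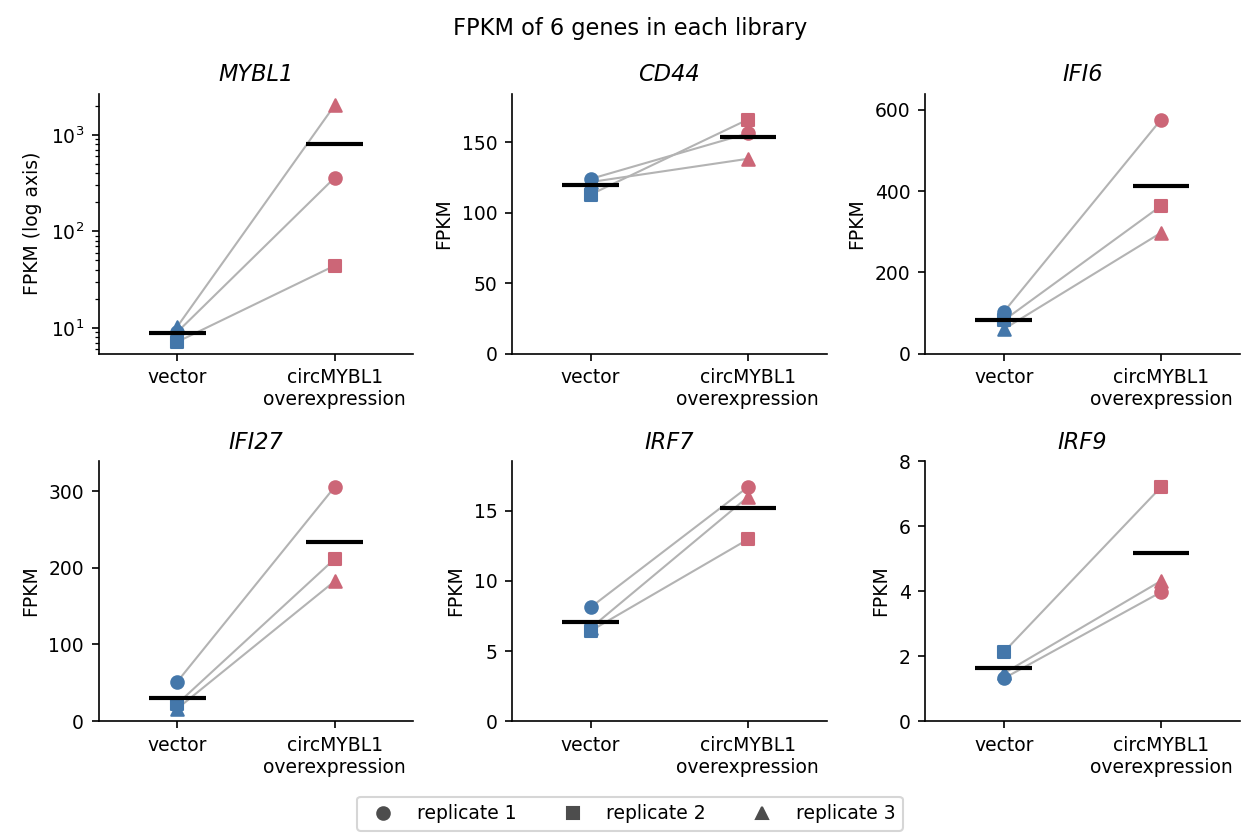
FPKM of MYBL1 (log axis), CD44, IFI6, IFI27, IRF7 and IRF9 in each of the 3 vector and 3 circMYBL1 overexpression libraries. Marker shape gives the replicate number, gray lines join same-numbered libraries and black bars are group means. All 6 genes were higher in the overexpression library of each of the 3 pairs.

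Genes of the type I interferon response, the antiviral program downstream of the interferon receptor, formed the list with the smallest adjusted p. With the replicate block, IFI6, an interferon-induced mitochondrial protein, rose from 81.7 ± 21.3 to 413 ± 146 FPKM (log2 fold change 2.30, SE 0.09, limma, adjusted p = 5.67e-06), and IFI27, another interferon-induced gene, rose from 30.2 ± 18.8 to 233 ± 64.2 FPKM (3.04, SE 0.14, adjusted p = 1.08e-05). IRF7, a transcription factor that amplifies interferon production, rose from 7.06 ± 0.918 to 15.2 ± 1.98 FPKM, and IRF9, the DNA-binding subunit of the interferon-activated ISGF3 complex, rose from 1.64 ± 0.430 to 5.16 ± 1.77 FPKM (both adjusted p = 0.00569). OAS2, an antiviral oligoadenylate synthetase singled out after its values were seen, rose from 10.5 ± 6.34 to 21.4 ± 9.20 FPKM (adjusted p = 0.0167; adjusted p = 0.0501 without a trend). Without the block none of these 5 passed, with adjusted p = 0.672 for IFI6 and for IFI27 and 1.0 for the other 3. In the block fit all 5 calls ended without a filter on low values (adjusted p = 0.132 for IFI6 and 0.279 for IFI27). Those of IRF7, IRF9 and OAS2 also ended after GC and length correction (limma, adjusted p = 0.108, 0.0563 and 0.0851). IRF9 shares exon sequence with AL136295.5 in the annotation, so its value is uncertain, and the summed FPKM of the 2 genes was 7.79 ± 1.51 against 12.8 ± 1.79.

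Of the 39 tested interferon genes, 36 were higher on average and 29 were higher in 3 of 3 pairs. The list rose as a set by camera with the preset correlation (mean log2 fold change 0.49, median 0.31, adjusted p = 2.21e-19). With an estimated correlation between its genes the list did not pass (adjusted p = 0.523, unadjusted p = 0.0769), nor did it with the block (adjusted p = 0.578, unadjusted p = 0.0538). That correlation was estimated at 0.544 without the block and 0.192 with it, both above the preset value. The camera p at the preset correlation is therefore likely too small for this list. By fry the adjusted p was 0.909 without the block and 0.478 with it. Over all genes 0 members passed without the block and 5 with it. Adjusted over the list alone, 4 rose without the block and 21 with it. The pair means were 0.48, 0.35 and 0.64. Without the block the list mean was 0.31 without vector replicate 1 and 0.27 without overexpression replicate 2, and 0.78 without vector replicate 2, with the camera call kept in each (adjusted p = 0.000105 or less). Members did not move alike. Of 4 members chosen after their values were seen, ISG15, a ubiquitin-like modifier, read 650.3 ± 165 against 869 ± 176 FPKM, while the antiviral IFIT1, IFIT2 and IFIT3 gave log2 fold changes of 0.05, 0.09 and 0.11, and OASL and DDX60, named by the rule, gave -0.14 and -0.15.

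**Figure D3:**
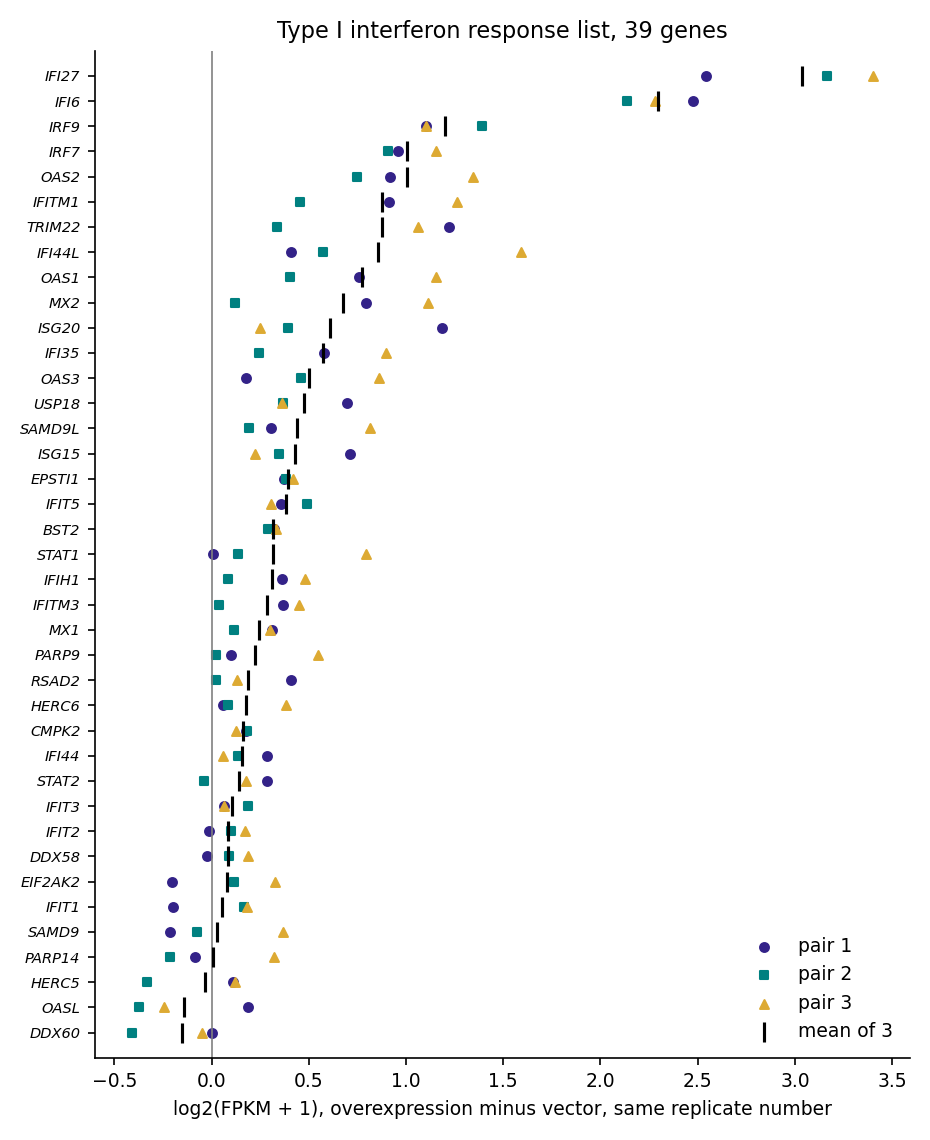
Difference of log2(FPKM + 1), overexpression minus vector library of the same replicate number, for the 39 tested genes of the type I interferon response list. Marker shape and color give the pair and the black tick is the mean of the 3 pairs. IFI27 and IFI6 have the largest means, 3.04 and 2.30, and 36 genes have a mean above 0.

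Across all 12064 tested genes, limma without the block called 0 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.672. At an unadjusted p under 0.05 there were 65 genes, 49 higher and 16 lower, where chance among unrelated libraries would give 603. The groups' ranges did not overlap for 403 genes (301 higher, 102 lower), which is 3.34% against the 10% that chance gives for 3 against 3 unrelated libraries. Neither chance value holds for these libraries, since same-numbered libraries of the 2 groups vary together, which makes ranges overlap. With the replicate block, 12 genes were called, 11 higher and 1 lower, and all 12 changed at least 2-fold; 868 had an unadjusted p under 0.05. After a correction of each library for GC content and length, added after the data were seen, 2 of the 12 genes passed in the block fit, IFI6 and IFI27. The 2 loci without a known GC content were not tested. The other 8 missed the threshold (adjusted p = 0.0563 to 0.117) with log2 fold changes close to those before: IRF9 1.20 before and 1.13 after, CCL3 1.03 and 1.001, DHRS2 1.37 and 1.31, OAS2 1.005 and 1.005, AL022238.4 1.07 and 1.02, ATXN7 -1.55 and -1.56, MYBL1 5.04 and 5.06 (SE 0.66 and 0.76), and IRF7 1.01 and 0.86, with SEs of 0.10 to 0.18 before and 0.11 to 0.19 after apart from MYBL1. On the same 11166 genes without the correction all 10 passed, with 8.22 prior degrees of freedom against 5.38 with it, and fewer degrees of freedom raise p at the same fold and spread. The block fit called 0 genes without a filter on low values, 23 with a stricter filter, and 148 without replicate 2 of both groups. The last count comes from a fit with few residual degrees of freedom and is unreliable. Across genes, which are not independent replicates, the log2 ratio followed GC content in pair 1 (Spearman 0.528) and less in pairs 2 and 3 (0.107 and -0.09).

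Besides MYBL1 and the 5 interferon genes, the block fit called 5 genes higher and 1 lower, and all but ATXN7 were singled out after their values were seen. CCL3, a chemokine that attracts monocytes, rose from 6.66 ± 5.30 to 13.4 ± 9.13 FPKM (log2 fold change 1.03, adjusted p = 0.0167). CCL3 has the near-identical copy CCL3L1, so its value is uncertain, and the 2 summed gave 44.6 ± 32.8 against 68.2 ± 40.0 FPKM. Without the block the log2 fold change of CCL3 was 0.11 without vector replicate 2, 0.59 without overexpression replicate 1 and 1.80 without overexpression replicate 2. Its block call ended with a pseudocount of 0.1 (1.36, adjusted p = 0.161) and under TPM (1.20, adjusted p = 0.0873). DHRS2, a short-chain dehydrogenase/reductase, rose from 5.88 ± 4.94 to 18.2 ± 18.4 FPKM (1.37, adjusted p = 0.0167). Without the block its log2 fold change was 0.61 without vector replicate 2 and 0.60 without overexpression replicate 1, and the block call ended without a trend (adjusted p = 0.0501). A pair of loci that the deposited table adds to the annotation, Homo_sapiens_newGene_7086 (1.50, adjusted p = 0.000184) and Homo_sapiens_newGene_6805 (1.10, adjusted p = 0.0197), have no position in the sources used here. The call of the latter ended without replicate 1 or 3 of both groups (adjusted p = 0.0834 and 0.0600) and under quantile scaling (adjusted p = 0.0543). AL022238.4 (1.07, adjusted p = 0.0384; adjusted p = 0.0906 without replicate 3 of both groups) shares exons with ADSL and SGSM3, and the sum of the 3 was 23.5 ± 2.99 against 22.4 ± 2.74 FPKM.

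ATXN7, a subunit of the SAGA coactivator complex, fell under the identifier ENSG00000163635 from 2.43 ± 0.370 to 0.185 ± 0.248 FPKM (log2 fold change -1.55, SE 0.18 with the block, adjusted p = 0.0152). With a pseudocount of 0.1 the log2 fold change was -3.48 and the call ended (adjusted p = 0.0827), as it did without a filter on low values (adjusted p = 0.814) and after GC and length correction. A further ATXN7 identifier, ENSG00000285258, overlaps it and read 2.38 ± 1.42 against 4.13 ± 1.07 FPKM. The 2 summed to 4.80 ± 1.60 against 4.31 ± 1.21 FPKM, so the fall of the identifier is not a fall of the summed gene. The remaining genes with the smallest unadjusted p did not pass in either fit. VPS33B, a vesicle-sorting protein, gave 0.56 (block adjusted p = 0.218), and the sum with the overlapping AC068831.7 differed by 0.06. On the lower side were MALL (-0.59), G3BP1, a stress granule protein (-0.49), the translation elongation factor EEF1A1 (-0.65, 3903 ± 763 against 2467 ± 348 FPKM), TENT5B (-0.60) and the transcription factor MAZ (-0.36), with block adjusted p between 0.164 (MALL) and 0.325 (MAZ).

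Genes of carbon and sterol metabolism were slightly higher in the overexpression libraries. The cholesterol biosynthesis list rose by camera with the preset correlation (mean log2 fold change 0.21, 25 of 25 genes higher, adjusted p = 3.35e-07), as did hypoxia targets (0.18, 23 of 24 higher, adjusted p = 0.000166) and glycolysis enzymes (0.16, 19 of 20 higher, adjusted p = 0.000389). With an estimated correlation each gave an adjusted p of 0.523 (cholesterol and hypoxia) or 0.525 (glycolysis). No member of these 3 lists passed over all genes in either fit. INSIG1, a sterol sensor of the endoplasmic reticulum, read 60.5 ± 7.79 against 78.4 ± 5.93 FPKM, and the sterol enzyme FDPS 215 ± 41.8 against 270.0 ± 39.3. NDRG1, a hypoxia-responsive gene, read 69.1 ± 14.2 against 91.3 ± 7.91 FPKM, HILPDA gave a log2 fold change of 0.39 and ADM, also a hypoxia target, gave -0.02. The neuronal enolase ENO2 read 10.3 ± 1.96 against 13.5 ± 2.10 FPKM, the lactate exporter SLC16A3 gave 0.22 and LDHB gave -0.02. Adjusted over the list alone, the block fit called 3 cholesterol genes, 2 hypoxia genes and 0 glycolysis genes. Cholesterol, hypoxia and glycolysis genes differed by 0.21, 0.27 and 0.24 in pair 1, by 0.37, 0.25 and 0.24 in pair 2 and by 0.04, 0.01 and 0.01 in pair 3, and without vector replicate 2 the means were 0.08, 0.11 and 0.04 and the calls ended (adjusted p = 0.379, 0.175 and 0.897). Of the 9 other splits of the 6 libraries into 3 and 3, the 4 with both libraries numbered 2 on one side gave 9 to 15 called lists, and the 5 that part these 2 libraries, as the real split does, gave 3 to 6 against its 8. The glycolysis call also ended without overexpression replicate 1 (0.09, adjusted p = 0.159) and, in the block fit, without replicate 2 of both groups (0.12, adjusted p = 0.0596).

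Mitochondrially encoded mRNAs were lower and nuclear-encoded respiratory genes slightly higher. All 13 mitochondrially encoded mRNAs were lower, and the list fell by camera with the preset correlation (mean log2 fold change -0.21, adjusted p = 5.23e-07; adjusted p = 0.523 with an estimated correlation). MT-ND6 read 546 ± 69.9 against 421 ± 98.1 FPKM and MT-ND5 747 ± 57.8 against 609 ± 109, both subunits of complex I. Over all genes 0 of the 13 passed in either fit, and adjusted over the list alone 3 fell with the block. The pair means were -0.32, -0.25 and -0.05, and the list mean was -0.08 without overexpression replicate 1 (adjusted p = 0.00776) and -0.32 without overexpression replicate 3 (adjusted p = 2.51e-10). The mitochondrial share of all FPKM ranged from 5.64% in overexpression replicate 1 to 10.2% in vector replicate 2. Nuclear-encoded oxidative phosphorylation genes rose (mean 0.09, 42 of 46 higher, adjusted p = 0.0123; adjusted p = 0.882 with an estimated correlation). COX5A, a subunit of cytochrome c oxidase, gave 0.23 and NDUFS1 of complex I 0.40 (7.82 ± 0.633 against 11.1 ± 4.29 FPKM; 0.13 without overexpression replicate 1), against -0.17 for NDUFV2 and -0.15 for ATP5ME. The pair means were 0.13, 0.06 and 0.07. That list's call ended without vector replicate 2 (0.03, adjusted p = 0.992), without vector replicate 3 (0.07, adjusted p = 0.599) and without overexpression replicate 1, where the mean was -0.02, and it also ended under TMM (adjusted p = 0.0564) and quantile scaling (adjusted p = 0.118). In the block fit it ended without replicate 3 of both groups (0.10, adjusted p = 0.104) and under quantile scaling (adjusted p = 0.0796).

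Ribosomal protein and mitotic genes were slightly lower. The cytosolic ribosomal protein list fell (mean log2 fold change -0.05, 44 of 63 lower, camera adjusted p = 0.00142; adjusted p = 0.882 with an estimated correlation), with RPS23 at 265 ± 28.0 against 171 ± 88.4 FPKM and RPL23 at 242 ± 69.4 against 173 ± 43.5. Genes of this family have many processed copies, so single values are uncertain. RPS15A and RPS15 gave 0.14 and 0.10. The pair means were -0.09, -0.07 and 0.02. The mean turned to 0.04 without vector replicate 1 and 0.05 without overexpression replicate 2, and the call ended without a filter on low values (adjusted p = 0.0974) and, in the block fit, without replicate 1 or 2 of both groups (adjusted p = 0.193 and 0.0828). The G2/M list fell (-0.04, 37 of 54 lower, adjusted p = 0.00233; adjusted p = 0.525 with an estimated correlation), with CKAP2 at -0.18 and PSRC1 at -0.23 against CDC25C at 0.16 and HJURP at 0.12. Its pair means were -0.13, 0.06 and -0.05, so pair 2 went the other way, and its mean was 0.00072 without vector replicate 1 and, in the block fit, 0.0086 without replicate 1 of both groups. The G2/M call also ended with library weights in either fit and, with the block, after GC and length correction (camera, adjusted p = 0.0656). No member of either list passed over all genes, and adjusted over the list alone 1 ribosomal gene fell with the block. G1/S genes, by contrast, did not pass (mean 0.03, 30 of 47 higher, adjusted p = 0.978), with CDC6 at 0.20 and UHRF1 at -0.25, except without overexpression replicate 1, where the list fell (-0.02, adjusted p = 0.0298; adjusted p = 0.683 with an estimated correlation).

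With all 6 libraries as deposited, a further 2 lists were called with the replicate block and not without it. Mesenchymal genes fell (mean log2 fold change -0.10, 12 of 18 lower; adjusted p = 0.0753 without and 0.00514 with the block), including TWIST1, a mesenchymal transcription factor, at 5.63 ± 1.18 against 4.47 ± 1.36 FPKM and ZEB1 at -0.26, while ITGA5 and LOX gave 0.27 and 0.13. Inflammatory cytokines and NF-kB targets rose (0.15, 22 of 25 higher; adjusted p = 0.142 without and 0.00171 with the block), with the NF-kB subunit gene NFKB2 at 19.9 ± 6.09 against 26.6 ± 8.62 FPKM, LIF at 0.17, BCL3 at -0.06 and IL1A at -0.08. With the block and an estimated correlation both gave adjusted p = 0.854. The pair means were -0.08, -0.05 and -0.17 for mesenchymal and 0.37, 0.05 and 0.05 for inflammatory genes. The inflammatory call ended without replicate 1 of both groups (0.05, adjusted p = 0.460) and the mesenchymal call without replicate 3 (-0.07, adjusted p = 0.0805) and without a filter on low values (-0.07, adjusted p = 0.0668). Without the block the inflammatory list rose without a filter on low values (0.14, adjusted p = 0.0473), without vector replicate 3 (0.25, adjusted p = 0.0384) and without overexpression replicate 2 (0.31, adjusted p = 0.000819), and the mesenchymal list fell after GC and length correction (-0.15, adjusted p = 0.0464). With an estimated correlation these calls ended too (adjusted p = 0.490 to 0.854). No member of the 2 lists passed over all genes, and adjusted over the list alone 1 mesenchymal gene fell with the block.

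**Figure D4:**
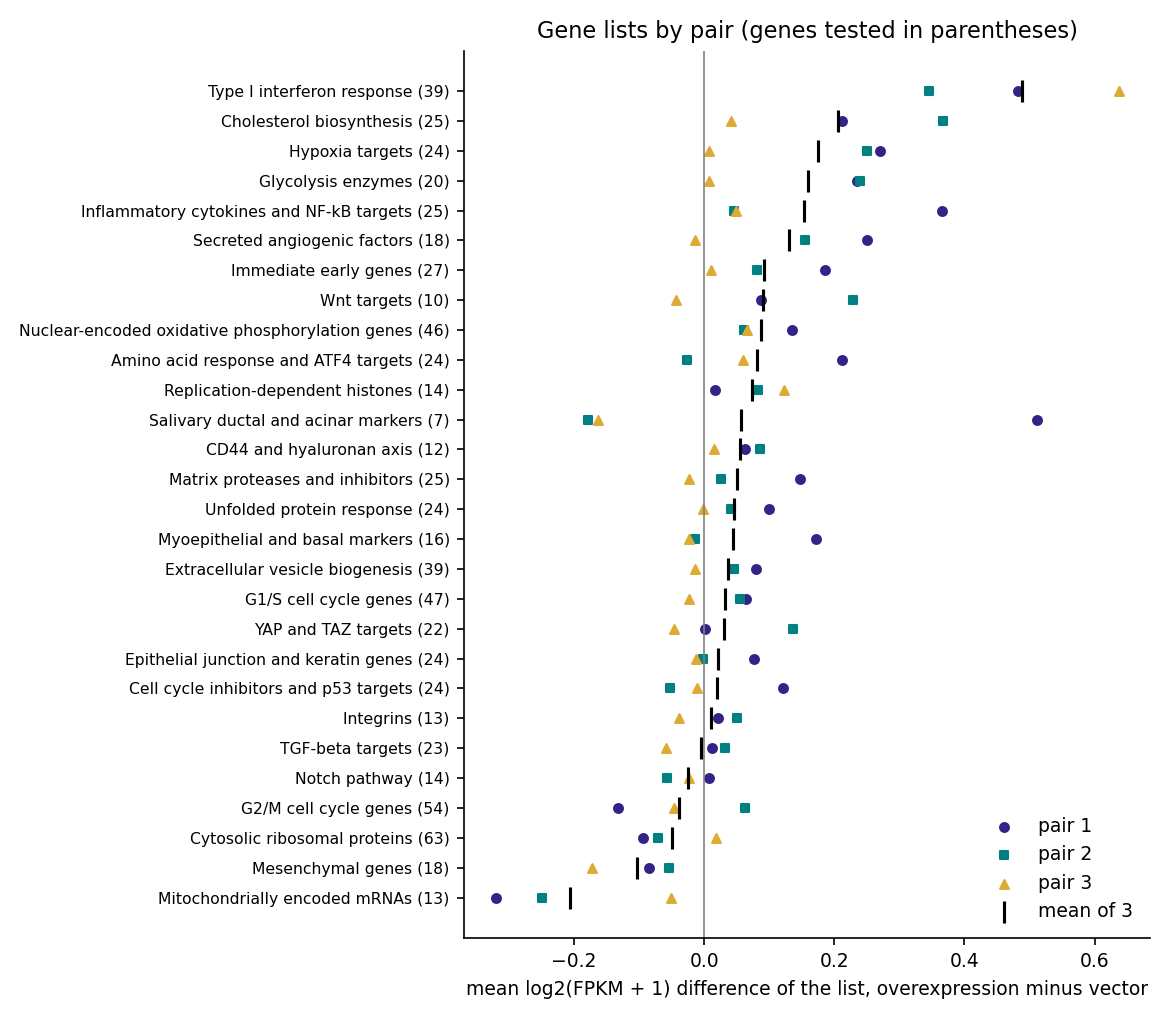
Mean difference of log2(FPKM + 1), overexpression minus vector, of 28 gene lists in each of the 3 pairs, with the number of tested genes in parentheses. The MYB family list, which holds MYBL1, is left out for scale. The interferon list has the highest mean, 0.49, and the mitochondrially encoded mRNAs the lowest, -0.21.

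With all 6 libraries, lists tied to adhesion, lineage and metastasis did not pass in either fit (camera, preset correlation, adjusted p without the block in each case). The list of extracellular vesicle biogenesis genes had a mean log2 fold change of 0.04 (27 of 39 higher, adjusted p = 0.771), with the ESCRT genes VPS28 and VPS25 at 0.24 and 0.21 and VPS37B and CHMP4A at -0.10 and -0.28. Secreted angiogenic factors had a mean of 0.13 (12 of 18 higher, adjusted p = 0.434), with ANGPTL4 at 0.51 and VEGFC at 0.29 against FGF2 at -0.12. Matrix proteases and their inhibitors had 0.05 (15 of 25, adjusted p = 0.768), with CTSS at 0.42 and the urokinase receptor PLAUR at 0.35 against ADAM9 at -0.15. Integrins had 0.01 (7 of 13, adjusted p = 0.978), with ITGB2 at 0.14 and ITGAV at -0.15. Epithelial junction and keratin genes had 0.02 (14 of 24, adjusted p = 0.975), with PKP3 at 0.31 and DSG2 at -0.27. Myoepithelial and basal markers had 0.04 (10 of 16, adjusted p = 0.978), with LAMB3 at 0.32 and KRT5 at -0.34. Salivary ductal and acinar markers had a mean of 0.06 and a median of -0.07 (3 of 7, adjusted p = 0.828), with CST3 at 0.36 and SLC12A2 at -0.07, and a pair 1 mean of 0.51 against -0.18 and -0.16. Leaving out libraries gave calls for 3 of these lists: matrix proteases rose without vector replicate 2 (0.19, adjusted p = 0.0148), and in the block fit salivary markers fell without replicate 1 of both groups (-0.17, adjusted p = 0.0453) and angiogenic factors rose without replicate 3 of both groups (0.20, adjusted p = 0.0457). With an estimated correlation the adjusted p of these 3 was 0.776, 0.883 and 0.883. Adjusted over the list alone, 1 myoepithelial gene fell with the block.

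Signaling and stress lists did not pass either with all 6 libraries as deposited. Notch pathway genes had a mean log2 fold change of -0.02 (5 of 14 higher, adjusted p = 0.478), with HES4 at 0.21 and JAG1 at -0.22. TGF-beta targets had a mean below 0 and a median of 0.03 (13 of 23, adjusted p = 0.496), with SMAD3 at 0.12 and SKIL at -0.42. YAP and TAZ targets had 0.03 (13 of 22, adjusted p = 0.771), with NT5E at 0.50 and CTGF at -0.31. Wnt targets had 0.09 (8 of 10, adjusted p = 0.771), with SOX9 at 0.31 and MYC at -0.22. Immediate early genes had 0.09 (18 of 27, adjusted p = 0.169), with NR4A1 at 0.42 and JUND at 0.33 against EGR1 at -0.19. The unfolded protein response list had 0.05 (16 of 24, adjusted p = 0.689), with CRELD2 at 0.33 and SEL1L at -0.19. ATF4 targets of the amino acid response had 0.08 (18 of 24, adjusted p = 0.434), with CEBPB at 0.53 and the cystine transporter SLC7A11 at -0.25. Cell cycle inhibitors and p53 targets had 0.02 (14 of 24, adjusted p = 0.994), with CDKN1A at 0.34 and CDKN2B at -0.24. Replication-dependent histones, many of which lack poly(A) tails, had 0.07 (8 of 14, adjusted p = 0.806), with HIST1H1C at 0.44. For the myoepithelial and the YAP and TAZ lists the camera direction was down although mean and median lay above 0, since camera compares a list with all other genes. For TGF-beta targets it was down with a median above 0, and for salivary markers up with a median below 0. With the block the direction was down for the epithelial, integrin and p53 lists, whose means lay above 0. Adjusted over the list alone, 1 YAP and TAZ target, 1 Wnt target and 2 histones rose with the block.

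Some of these lists passed under other settings by camera with the preset correlation, and none did with an estimated correlation (adjusted p = 0.538 to 0.940 in the settings named here). After GC and length correction Notch pathway genes fell in both fits (mean log2 fold change -0.11, adjusted p = 0.00957 without and 0.00467 with the block). YAP and TAZ targets fell without vector replicate 2 (-0.19, adjusted p = 0.00213) and TGF-beta targets fell without overexpression replicate 1 (-0.06, adjusted p = 0.0442). Without vector replicate 3 and without overexpression replicate 2, ATF4 targets rose (0.18 and 0.28, adjusted p = 0.0185 and 2.11e-05), as did immediate early genes (0.21 and 0.24, adjusted p = 0.00214 and 0.00124). With the block, ATF4 targets rose without replicate 2 of both groups (0.14, adjusted p = 0.0276).

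Few markers of other cell types passed the filter on low values. Of 12 fibroblast markers 2 were tested, COL1A1 at 6.56 ± 3.94 against 5.25 ± 3.02 FPKM and MFAP5 at 1.49 ± 0.415 against 1.61 ± 0.722. Of 13 endothelial markers 0 passed the filter, and of 16 leukocyte markers 2 did, CD68 at 7.54 ± 0.447 against 8.43 ± 2.18 FPKM and CSF1R at 1.30 ± 0.303 against 1.62 ± 0.464. These lists had too few genes for a test.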

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

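Alternatives within the block fit, among them that on genes with a known GC content only, the GC correction and the estimated correlation under each other alternative were chosen after the data were seen; the others were planned. The count of genes at an adjusted p under 0.05 was 0 without the block under each pseudocount, filter, scaling, eBayes and GC setting. With library weights it was 346, of which 42 changed at least 2-fold, the lists called were 2 and MYBL1 passed at 7.02, but the weighting did not converge and gave vector replicate 3 a weight of 25.1, which makes these calls unreliable. Leaving out a library gave 0 to 1 genes, and the same with a 2-fold limit: RPL36A-HNRNPH2 without vector replicate 1 and Homo_sapiens_newGene_7073 without overexpression replicate 2, both with values of 0 in some libraries. With the replicate block 12 genes passed, all at least 2-fold, MYBL1 among them at 5.04, and 10 lists instead of 8; CD44 did not pass in either fit, with adjusted p from 0.0991 to 1.0 over 17 alternatives and from 0.265 to 0.814 over 13 in the block fit. Beside the calls given here and in the results, the block changed no other call.

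Within the block fit, 0 genes passed without a filter (0 with a 2-fold limit; MYBL1 5.04, adjusted p = 0.814), when 23155 genes were tested, 23 under the stricter filter, and 2 (both at least 2-fold) after GC and length correction, when loci without a known GC content were not tested; without the correction 10 of the genes with a known GC content passed. MYBL1 also missed the threshold after that correction (5.06, adjusted p = 0.117) and without a trend (5.04, adjusted p = 0.0883). Leaving out both libraries of a number gave 14 to 148 genes, 12 to 33 at least 2-fold, and MYBL1 between 3.82 and 6.33, missing the threshold without replicate 1 (4.98, adjusted p = 0.0587). The 148 came without replicate 2 and include the 12. A block fit without one replicate number keeps 2 libraries per group and few residual degrees of freedom. Its counts and p-values are therefore unreliable. No list passed with an estimated correlation (0) or by fry (0), in either fit, and 0 passed with an estimated correlation under each other alternative and each left-out library. For the lists called without the block, the estimate ran from 0.0853 (G2/M) to 0.544 (interferon), all above the preset value. For those called with the block, it ran from -0.0139 (ribosomal proteins) to 0.754 (mitochondrial mRNAs). In the block fit only the ribosomal and nuclear oxidative phosphorylation (-0.00971) lists lay below the preset value. Where the estimate lies above it, the preset p is likely too small. The interferon mean kept its direction and its camera call under all 17 alternatives without the block (0.27 to 0.78) and all 13 with it (0.41 to 0.56). Of 119 alternatives for the other 7 called lists 100 kept the call and 14 lost it, and in 5 it ended with a mean of turned sign. With the block, of 117 for 9 lists 106 kept it, 10 lost it and in 1 it ended with a mean of turned sign. The ribosomal mean was 0.0060 with library weights and ran from -0.13 to 0.0458 when libraries were left out, the G2/M mean from -0.0663 to 0.00072 (block, -0.0892 to 0.00857) and the nuclear oxidative phosphorylation mean from -0.0161 to 0.17. The cause was not tested for any of these. Lists not called with all 6 libraries as deposited were called under some alternatives; these are given in the results. For 17 named genes other than CD44 and MYBL1, which did not pass without the block, 25 of 281 alternatives gave a call and 0 reversed. With the block, 27 of 213 lost a call, 11 of them without a filter on low values and 7 after GC and length correction, 3 gave one, all without replicate 2 of both groups, and 0 reversed. In either fit the median shift of all genes was under 0.1. Unknown depth leaves the error of low values open.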

Other observations

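The GC and length correction, the contrast of the libraries numbered 2 and the tests on other cell types, on the order of MYBL1, on culture state and on the replicate-number axis were chosen after the data were seen; the tests on scaling and on other splits of the libraries were set beforehand. Replicate number, not group, held most of the variation, with 5605 of 12064 genes called for it. In the libraries numbered 2 of both groups AQP3, a water and glycerol channel, read 202 and 132 FPKM in vector and overexpression replicate 2 and a mean of 5.85 in the other 4 libraries. KRT13, a keratin of stratified mucosa, read 195 and 111 against 15.8, and LY6D, PSCA, KLK10, the sodium channel subunit SCNN1A and the mucin MUC1 differed by 3.42, 3.09, 3.04, 3.04 and 2.98 on the log2 scale. SERPINB2, an inhibitor of plasminogen activation, went the other way, at 17.4 and 31.4 FPKM against 292, as did the matrix protein THBS1 (-3.03), the polyamine enzyme ODC1 (-3.02), the AP-1 genes FOSL1 (-2.56) and JUN (-2.25), and the cytokines CSF2 (-2.11) and IL6 (-2.05). These genes were chosen after their values were seen, and limma with number as a term gave adjusted p of 4.52e-05 or less for each.

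By list, 12 of 29 lists were called between the libraries numbered 2 and the others, 4 higher and 8 lower. The libraries numbered 2 were higher in type I interferon response (mean log2 difference 0.77, camera, preset correlation, adjusted p = 4.73e-07), epithelial junction and keratin genes (0.45, adjusted p = 0.00649), myoepithelial and basal markers (0.46, adjusted p = 0.0427) and matrix proteases (0.40, adjusted p = 0.00422), and lower in YAP and TAZ targets, given below, ATF4 targets (-0.51, adjusted p = 3.21e-05), immediate early genes (-0.43, adjusted p = 0.00253), inflammatory genes (-0.39, adjusted p = 0.0232), glycolysis (-0.30, adjusted p = 0.00296), cholesterol biosynthesis (-0.26, adjusted p = 0.00433), nuclear oxidative phosphorylation (-0.20, adjusted p = 0.00253) and ribosomal proteins (-0.27, adjusted p = 4.73e-07). Salivary ductal and acinar markers did not pass (1.19, adjusted p = 0.0900). With an estimated correlation 0 of the 12 passed (adjusted p = 0.565 to 0.711). By fry 13 lists passed (adjusted p = 0.0344 to 0.0429), among them 9 of the 12; the inflammatory, glycolysis and cholesterol lists did not.

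The replicate numbers make a pattern that GC content or length does not account for, since after correction 53.3% of the 11166 genes with a known GC content were called for number, against 47.8% of the same genes before. Culture density or growth state is a candidate explanation: targets of YAP and TAZ, which fall in dense cultures, were lower in the libraries numbered 2 (mean log2 difference -0.59, adjusted p = 0.000122 by camera with the preset correlation, adjusted p = 0.565 with an estimated one, 0.0344 by fry). The labels name no density, passage or day, so this stays a hypothesis.

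The higher interferon genes in the overexpression libraries are the pattern most open to follow-up. The list mean was 0.47 after GC and length correction in the block fit and at least 0.45 under TPM, TMM and quantile scaling, against 0.49 as deposited, which argues against sequence bias or scaling as the whole cause. Summed FPKM of 29 leukocyte and endothelial markers differed by 1.36, which is 0.255% of the summed rise of IFI6 and IFI27, so admixed cells of these types do not account for it. A shift along the replicate-number axis, on which the list also moves, would need a slope of 0.63 across genes, and the slope over the 12025 genes outside the list was -0.0711. Explanations that stay open include that the overexpressed RNA or its construct raises interferon signaling, though the control libraries carry an empty vector too. A difference in culture or handling between the groups, other than along the replicate-number axis, was not tested and stays open as well. The list mean differed by 0.88 between vector replicate 2 and the other vector libraries, without overexpression, against 0.49 between the groups. The pair means follow the order of the MYBL1 ratios, with 0.29 between the pairs with the most and the least MYBL1. However, 3 pairs cannot decide an order, and no library with an unrelated overexpressed RNA was analysed here.

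The smaller list shifts were also set against GC content, because in pair 1 the log2 ratio followed GC across genes (Spearman 0.528, against 0.107 and -0.09 in pairs 2 and 3; genes are not independent replicates). After correction without the block the means were 0.10 for glycolysis, 0.14 for hypoxia, 0.17 for cholesterol, 0.0629 for nuclear oxidative phosphorylation, -0.19 for mitochondrial mRNAs, -0.0859 for ribosomal proteins and -0.0401 for G2/M, each on the same side of the threshold as before, which argues against GC or length as the whole cause; in the block fit the G2/M list missed it (adjusted p = 0.0656), with the mean at -0.0401 after the correction and -0.0384 before. Of the 10 splits of the 6 libraries, 5, the real one with 8 lists included, gave at least 8. The 4 others, of which the highest gave 15, are the splits with both libraries numbered 2 on one side, which points to the structure of the replicate numbers; the 5 other splits that part these libraries gave 3 to 6. Each number is in both groups, and with the block the real split gave 10 lists, these 7 among them, and the 3 other ways of parting the pairs gave 4, 5 and 4. What stays open for these lists is a difference particular to single libraries, as 6 of the 7 calls, all but that of the mitochondrial mRNAs, end without one of them, and 4 ways cannot give a share under 0.05.

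For genes, all 10 splits gave 0 without the block, as the real one did. Of the 4 ways of parting the 3 pairs, 1, the real one, gave as many as 12 genes, and the highest other gave 0. For the interferon mean the same 1 of 4 reached 0.49, and the highest other was 0.26. Among the 10 splits without the block, 0.49 was not the largest absolute mean. Parting vector replicates 1 and 3 with overexpression replicate 1 from the rest gave 0.80, and with overexpression replicate 3 gave 0.60. These splits keep the libraries numbered 2 on one side, and the remaining splits gave 0.37 or less. With 10 splits or 4 ways no share can fall under 0.05.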
